A study of Mus musculus with 21 samples.

How the data were processed

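Prostate RNA from FVB/N males that carry a luciferase reporter driven by androgen response elements was measured on Illumina mouse bead arrays, a platform in which each probe is a set of beads coated with 1 oligonucleotide. The labels place 21 arrays in 6 groups and 2 experiments. In the genistein experiment, 3 arrays each came from castrated males given vehicle, castrated males given genistein, intact males given vehicle and intact males given genistein. In the estradiol experiment, 5 arrays came from intact males given vehicle and 4 from intact males given 17β-estradiol. Per the labels' protocols, genistein was injected under the skin for 5 days at 300 µg per mouse per day (10 µg/g body weight) in 0.1 ml of mineral oil with 2% dimethylsulfoxide, starting 4 days after surgery in castrated males. Estradiol was given for 4 days at 0.25 µg per mouse per day (10 µg/kg body weight) in mineral oil with 0.5% ethanol. Prostates were taken 24 hours after the last injection from males 8 to 12 weeks old. The labels do not say whether an array holds RNA of a single animal or of a pool, nor which lobes were dissected, so the p-values measure the spread between these samples, which may in part be technical.

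The authors deposited, for each experiment, a table with an average bead intensity and a detection p-value for each of 45259 probes on each array. The intensity values are linear and neither background-subtracted nor normalized between arrays, as the values themselves show. The detection p-values, per the file headers, stand beside each array's intensity; how they were computed is not given in the sources used here. BeadStudio is named in the submitters' processing notes, without a version, and the labels' protocols name biotin-labelled cRNA and a column-based RNA extraction with DNase. A further table from the authors holds processed intensity values of the same arrays. Per the values, these are linear, were background-subtracted (values reach below 0) and were brought to 1 common distribution within each experiment, since the array medians lie between 9.0 and 9.1 in the genistein experiment and between 15.1 and 15.2 in the estradiol experiment. Each column had a rank correlation of 1 with the unprocessed values of its own array; the method behind the processed values is not given in the sources used here. No column of an unknown sample was used, and no genome build applies.

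The unprocessed intensities were analysed in R 4.3.3 with limma 3.58.1; jsonlite 2.0.0 read the labels. Within each experiment the function neqc estimated the background from the detection p-values, corrected it with normexp and an offset of 16, quantile-normalized the arrays and took log2. Probes with a detection p-value under 0.05 on at least 3 arrays of the experiment were kept, 22332 in the genistein experiment and 21835 in the estradiol experiment. Gene symbols came from the platform's annotation table, in which 34872 probes have 1 symbol, 18 have several and 10369 have none; looking symbols up again by gene identifier changed 0 of them. A gene with several kept probes was represented by the brightest, and a probe without a single symbol was tested under its own identifier. This left 15406 genes in the genistein experiment (12078 with a symbol), 15088 in the estradiol experiment (11839 with a symbol) and 14425 in both.

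Depth of an array is given by signal over background. Array medians ran from 99.4 to 109 in the genistein experiment and from 145 to 171.9 in the estradiol experiment, with 42.3% to 46.4% and 44.2% to 47.0% of probes detected. The correlation of an array with the other arrays of its group, over kept genes, averaged 0.982 to 0.991 and 0.956 to 0.988. The number of arrays limits the precision. By the array numbers in the labels the arrays lie on 5 chips: the castrated arrays share chip 1, the intact arrays of the genistein experiment share chip 2, the 4 estradiol arrays and vehicle arrays 1 and 2 lie on chip 3, vehicle arrays 3 and 4 on chip 4, and vehicle array 5 on chip 5. The genistein comparisons are thus made within a chip, castration and chip cannot be told apart, and the estradiol comparison can be made within chip 3 alone.

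Every adjusted p-value for a gene comes from limma (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes tested), with a threshold of 0.05. The 12 arrays of the genistein experiment entered 1 fit with 4 group means, the 9 arrays of the estradiol experiment another, and the 21 arrays, normalized together, a further one, used for the difference between the genistein and estradiol responses. A gene not detected on any array of a group has only a bound there; its change is then also given as at least N-fold, computed from normalized log2 values with the lowest detected signal of each array standing in for the undetected group where it was the higher. Residual degrees of freedom were 8, 7 and 15.

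A total of 27 gene lists was tested: mouse prostate secretory proteins, androgen receptor target genes of prostate epithelium, androgen-repressed and regression genes, cell cycle, polyamine metabolism, endoplasmic reticulum protein folding, cholesterol synthesis, fatty acid synthesis, estrogen-responsive genes, squamous differentiation, steroid receptors and steroid enzymes, xenobiotic and oxidative stress response, interferon response, apoptosis, immediate early genes, and markers of 12 cell types that a prostate dissection can hold. Each list was set against the other genes with camera at a correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 162 tests of 27 lists in 6 comparisons, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance in a single direction. With an estimated correlation no list was called in any comparison. Members counted as having risen or fallen passed the limma threshold over all genes; counts adjusted over the list alone are named as such. The genes named in each comparison are those with a symbol (not LOC, Gm or Rik names), an adjusted p under 0.05, a log2 change of at least 0.5 and groups that do not overlap, the 10 with the largest rise and the 10 with the largest fall; in addition up to 4 members of each list with the smallest p-values, and Esr1, Esr2 and Pbsn everywhere. Setd3, Cda, Cpsf4l and the transcripts that stood apart on single arrays were named after their values were seen.

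The groups, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Alternatives were no background correction, an offset of 50, median scaling, cyclic loess, no filter, a strict filter (detection p-value under 0.01 on every array of a group), the mean of a gene's probes, the authors' processed values, eBayes with trend and robust, array weights, the replicate number as a block, fits on only the arrays compared, the chip as a fixed or random block, only the chip that holds both groups, separate normalization of the experiments, and each array left out in turn. Added after the data were seen were fits without castrated genistein arrays 1 and 3, castration measured in genistein-treated males, and the number of lists called under each setting. Under median scaling, the median change of all genes moved to 0.14 for castration, 0.11 for genistein in intact males, -0.16 for the difference between the genistein responses and 0.16 for estradiol, against values within 0.05 of 0 after quantile normalization.

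The fits were tested on simulated data, 5 simulations per comparison with 200 changed genes each. Of genes changed by 1 log2 unit, 70.4% were recovered for genistein in castrated males, 66.0% for genistein in intact males, 70.1% for castration, 40.0% for the difference between the genistein responses, 68.1% for estradiol and 51.3% for the difference between genistein and estradiol. Of genes changed by 0.5 log2 units, 20.9%, 15.8%, 15.2%, 2.69%, 14.6% and 7.16% were recovered in the same order of comparisons. False calls averaged 4.6 to 7.4 genes, and a shifted list was found in 5 of 5 simulations of every comparison. Each gene was drawn independently of the others, so the list result does not cover lists whose genes move together. Neither fewer nor more than 200 changed genes were simulated. Castration changed 3259 genes, so its simulated shares do not describe that comparison. Correlations of changes across genes carry no p-value because genes are not independent replicates; 5 of them were computed. For those, 100 draws of unchanged groups were simulated, keeping the arrays that the comparisons share.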

Results

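Transcript levels were measured in 21 mouse prostate samples on bead arrays. The genistein experiment held castrated and intact males given the soy isoflavone genistein or vehicle, with 3 arrays in each of 4 groups. The estradiol experiment held intact males given vehicle (5 arrays) or 17β-estradiol (4 arrays). The title of the series presents genistein, a plant compound that binds estrogen receptors, as a modulator of the androgen receptor. The comparisons asked what castration, genistein with and without testes, and estradiol did to prostate transcripts. Between 42.3% and 47.0% of the probes were detected on an array. The main axis of variation in the genistein experiment carried 55.0% of the variance and separated castrated from intact males. In the estradiol experiment the first axis carried 37.4% of the variance and set vehicle array 1, at -63.6, apart from the other 4 vehicle arrays, at 9.75 to 22.8.

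Castration lowered transcripts of several secreted proteins. Probasin (Pbsn), an androgen-driven secretory protein of mouse prostate epithelium, fell by 4.64 on the log2 scale (SE 0.31, adjusted p = 3.53e-06), from a signal of 10.2 ± 0.50 (SD, n = 3) to 5.56 ± 0.56 (SD, n = 3). The blood group glycosyltransferase Abo fell by 6.87 (SE 0.27, adjusted p = 4.58e-08). In the same arrays the log2 changes were -6.36 (SE 0.285, adjusted p = 1.59e-07) for the apolipoprotein Apof and -6.17 (SE 0.32, adjusted p = 4.11e-07) for Wfdc3, of a protease inhibitor family. The secretoglobin Scgb2b27 fell by 5.85 (SE 0.63), and the trypsin inhibitor Spink1 fell by 5.43 (SE 0.55). The beta-defensin Defb10 was not detected on any castrated vehicle array and fell at least 23.1-fold. The protease inhibitor Spink5, likewise undetected, fell at least 14.9-fold. Tcaf3 and the gasdermin Gsdma, at log2 changes of -4.88 (SE 0.43) and -4.25 (SE 0.30), completed the 10 genes with the largest falls. In genistein-treated males, a contrast added after the data were seen, all 10 fell after castration as well, with log2 changes from -3.50 for Gsdma to -6.87 for Abo. That contrast compares the same pair of chips, so a chip difference would recur in it.

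The largest rises after castration were in Pate6, a member of a gene family of prostate and testis, and Ang4, a ribonuclease of the angiogenin family. Pate6 was undetected in intact vehicle males and rose at least 74.8-fold (log2 change 6.70, SE 1.22, adjusted p = 0.00274). Ang4 rose by 5.01 log2 units (SE 0.43, adjusted p = 1.78e-05). Next were Rprm, a gene of cell cycle arrest (4.45, SE 0.95), Abcg5 and Abcg8, the partners of a sterol transporter (4.17, SE 0.74, and at least 7.03-fold). The major urinary protein Mup2 rose by 4.11 (SE 0.53), while its 3 probes ranged from 0.38 to 4.11. The last of the 10 were the carboxylesterase Ces1e (3.84, SE 0.49), the chloride channel Best1 (3.16, SE 0.51), Olfm4 (at least 6.75-fold) and the amino acid oxidase Il4i1 (3.06, SE 0.65). For 8 of these 10 genes, all but Ang4 and Mup2, castrated genistein arrays 1 and 3 read at least 1 log2 unit below the lowest castrated vehicle array, as in Pate6 at 5.77 and 4.38 on those arrays and 11.22 on array 2. In genistein-treated males 3 of the 10 rose after castration, namely Ang4 by 4.98, Mup2 by 4.59 and Olfm4 by 1.54. Pate6 had a log2 change of 2.52 (SE 1.22, adjusted p = 0.165), Rprm of 0.04 and Il4i1 of -0.0022.

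**Figure D1:**
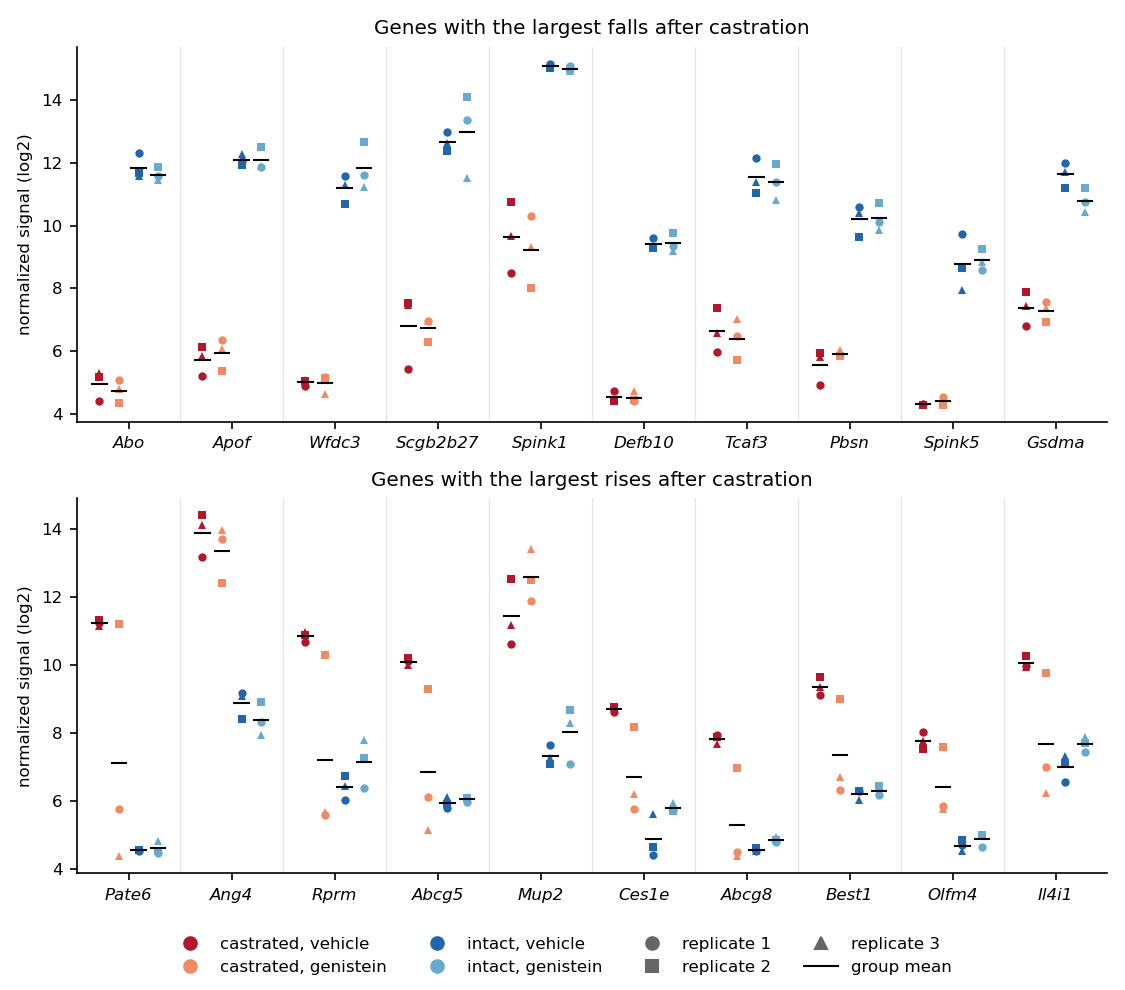
Normalized log2 signal (y axis) of the 10 genes with the largest falls and the 10 with the largest rises after castration (x axis), 1 point per array with the replicate number as its shape, and the group mean as a black bar, n = 3 per group. All 6 castrated arrays lie below all intact arrays for the 10 falls, while castrated genistein arrays 1 and 3 lie near the intact arrays for Pate6 and Rprm.

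In total 3259 of 15406 genes (21.2%) changed with castration in limma, 1713 higher and 1546 lower, of which 588 carry no gene symbol. A change of at least 1 log2 unit was found for 420 higher and 481 lower genes. Groups did not overlap for 39.5% of genes, where 10% is the share chance gives with 3 against 3 arrays. Castrated and intact arrays lie on different chips, so castration and chip cannot be told apart. Under median scaling the split was 2283 higher and 1053 lower. Without castrated vehicle array 1 the count was 2037. In genistein-treated males castration changed 3401 genes, of which 1997 had changed in the same direction in vehicle-treated males and 1 in the opposite direction, against 191 higher and 168 lower genes in overlaps of independent lists. Both contrasts compare the same pair of chips within a single fit, so a chip difference would recur in both. The overlap therefore cannot separate castration from chip.

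Gene groups tied to the secretory work of the gland were lower after castration. Of 14 measured mouse prostate secretory proteins, 11 fell, 0 rose and 3 did not pass (12 fell adjusted over the list alone). Their median log2 change was -2.54 (adjusted p = 3.92e-11 in camera, adjusted p = 0.182 with an estimated correlation). Timp4 fell by 4.17, Azgp1 fell by 3.75 and the beta-microseminoprotein Msmb fell by 2.97. Of 20 endoplasmic reticulum protein folding genes, 17 fell and 3 did not pass (17 fell adjusted over the list alone). Their median was -1.08 (adjusted p = 1.02e-12, adjusted p = 0.678 with an estimated correlation). Among them the chaperones Creld2 and Hsp90b1 fell by 2.93 and 1.39 and the disulfide isomerases Pdia6 and Pdia3 by 2.04 and 1.23. Polyamine metabolism, which supplies spermine to prostatic fluid, was lower for 5 of 6 genes (5 adjusted over the list alone, median -0.89, adjusted p = 0.00156, adjusted p = 0.318 with an estimated correlation). Odc1, its entry enzyme, fell by 1.11, Srm by 1.11 and Amd2 by 1.52. Of 19 androgen receptor target genes, 11 fell, 1 rose and 7 did not pass (11 and 1 adjusted over the list alone, median -0.62, adjusted p = 0.00121, adjusted p = 0.318 with an estimated correlation). They were led by Fkbp5, a co-chaperone of steroid receptors, at -3.59, Gnmt at -3.07, Slc45a3 at -1.16 and Abcc4 at -0.78. These 4 lists were also called in genistein-treated males, on the same pair of chips, with a median of -2.48 for the secretory proteins and -1.09 for protein folding.

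Markers of immune and vascular cells were higher after castration. Of 12 macrophage markers, 11 rose and 1 did not pass (12 rose adjusted over the list alone). Their median was 0.98 (adjusted p = 2.44e-06, adjusted p = 0.857 with an estimated correlation). Tyrobp rose by 1.46, Aif1 by 1.41, Lyz2 by 1.33 and Cd14 by 1.04. Of 6 lymphocyte markers 5 rose (6 adjusted over the list alone, median 1.13, adjusted p = 0.00147, adjusted p = 0.318 with an estimated correlation). The T cell receptor chains Cd3e, Cd3g and Cd3d rose by 1.48, 1.16 and 0.91. Endothelial markers rose for 3 of 11 genes (7 adjusted over the list alone, median 0.55, adjusted p = 0.0108, adjusted p = 0.938 with an estimated correlation). Cldn5 rose by 1.28. Immediate early genes rose for 6 of 13 (9 adjusted over the list alone, median 0.74, adjusted p = 0.00156, adjusted p = 0.857 with an estimated correlation). Socs3 rose by 0.81 and the transcription factor Klf6 by 1.14. Interferon response genes rose for 7 of 16 and fell for 1 (10 and 1 adjusted over the list alone, median 0.64, adjusted p = 0.00765, adjusted p = 0.938 with an estimated correlation). The transcription factor Irf1 rose by 0.92 and the immunoproteasome subunit Psmb8 by 0.87. Androgen-repressed and regression genes rose for 6 of 17 and fell for 1 (10 and 1 adjusted over the list alone, median 0.44, adjusted p = 0.0344, adjusted p = 0.938 with an estimated correlation). The growth factor binding protein Igfbp3 rose by 2.36 and Igfbp2 fell by 2.24. The fry test called 7 of the 10 lists, leaving out the endothelial, interferon and androgen-repressed lists. Of the 10 ways to split these arrays 3 against 3, the real one included, 2 called as many lists. The endothelial call ended without intact vehicle array 1 (median 0.39), and the androgen-repressed call ended without castrated vehicle array 1 (0.42), under median scaling (0.56) and with a strict filter. In genistein-treated males the lymphocyte, immediate early, interferon and androgen-repressed lists were not called, with medians of 0.54, 0.58, 0.49 and 0.27. There Cd79b had a log2 change of -0.0038 after a rise of 1.11 in vehicle-treated males.

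The other 17 lists were not called after castration. Among cell types, smooth muscle markers had a median of -0.19 (3 of 12 fell, Actg2 by 1.39, Tagln by 1.11 and Cnn1 by 0.91). Luminal epithelial markers had -0.04 (2 rose, 3 fell, among them Foxa1 by 1.03), basal epithelial markers 0.15 (1 of 12 fell, Lgals7 by 1.20), and fibroblast markers 0.27 (5 of 13 rose, Lum by 2.55). Adipocyte, skeletal muscle and red blood cell markers had medians of 0.36, -0.28 and -0.05, urothelial markers 0.85, and seminal vesicle transcripts -1.91. Cell cycle genes had a median of 0.35, cholesterol synthesis -0.20, fatty acid synthesis 0.61, estrogen-responsive genes -0.06, squamous differentiation 0.20, steroid receptors and enzymes -0.06, xenobiotic response 0.17 and apoptosis 0.08. For the xenobiotic and basal lists the mean lay below 0 while the median lay above it. The estrogen receptors Esr1 and Esr2 had log2 changes of -0.11 (SE 0.25) and -0.25 (SE 0.31) and did not pass.

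**Figure D2:**
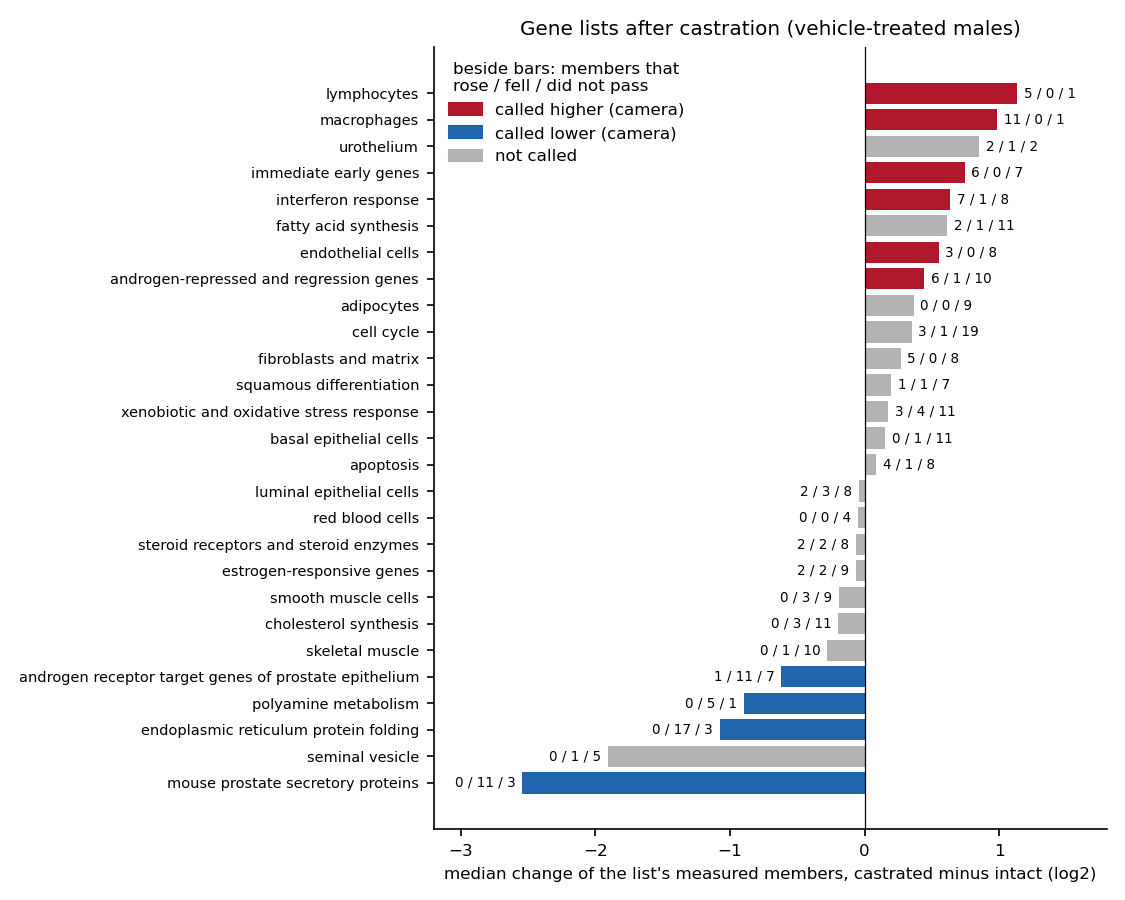
Median log2 change of the measured members of each of 27 gene lists (y axis) after castration in vehicle-treated males (x axis, castrated minus intact), with the numbers of members that rose, fell or did not pass beside each bar and colour showing the camera call at a correlation of 0.01. Of the lists, 6 were called higher and 4 lower, from 1.13 for lymphocyte markers to -2.54 for prostate secretory proteins.

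In castrated males genistein changed no single gene past the threshold, and seminal vesicle transcripts were among the widest differences. The seminal fluid proteins Svs2, Svs5 and Svs4 had log2 changes of -4.475 (SE 1.17), -4.20 (SE 1.135) and -3.66 (SE 1.02), with adjusted p of 0.2485 to 0.286 and n = 3 arrays per group. Cd52, a surface protein of lymphocytes that epithelium of the male tract also makes, had -3.50 (SE 0.85). The differences lay mostly in arrays 1 and 3 of the castrated genistein group. Svs2 read 5.97 and 4.65 on those arrays and 11.17 on array 2, against at least 11.53 on castrated vehicle arrays. Cd52 read 10.17, 9.83 and 14.21 against at least 14.84. Pbsn had a log2 change of 0.37 (SE 0.31, adjusted p = 0.763), Esr1 of 0.40 and Esr2 of -0.16. Limma called 0 of 15406 genes (lowest adjusted p = 0.119, for Cda), with 1459 at an unadjusted p under 0.05 and 17.5% of genes without overlap against 10% by chance.

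Camera called 6 lists for genistein in castrated males, all without a member past the threshold over all genes. Lower were seminal vesicle transcripts (6 of 6 below 0, 3 fell adjusted over the list alone, median -2.70, adjusted p = 0.00349, adjusted p = 0.857 with an estimated correlation). Also lower were endoplasmic reticulum protein folding (16 of 20 below 0, 1 fell adjusted over the list alone, median -0.22, adjusted p = 0.00147, adjusted p = 0.938 with an estimated correlation; Edem1 -0.76, Sdf2l1 -0.84) and lymphocyte markers (5 of 6 below 0, 1 fell adjusted over the list alone, median -0.26, adjusted p = 0.0366, adjusted p = 0.789 with an estimated correlation; Cd52 as above, Cd79b -0.65). Higher were skeletal muscle (11 of 11 above 0, median 0.34, adjusted p = 0.00751), adipocytes (8 of 9, median 0.46, adjusted p = 0.0344; Plin1 0.76, Lipe 0.65) and fatty acid synthesis (10 of 14, median 0.36, adjusted p = 0.0352; Fasn 0.85), each with 0 members adjusted over the list alone and adjusted p = 0.938 with an estimated correlation. Fry called 0 lists. Of the 10 ways to split these arrays 3 against 3, the real one included, 6 called as many lists, too few splits to judge a count. Of the other lists, secretory proteins had a median of 0.006 and androgen receptor targets of -0.03. Estrogen-responsive genes (-0.23, 2 fell adjusted over the list alone, adjusted p = 0.0904), smooth muscle (-0.20, adjusted p = 0.0692), luminal epithelial markers (-0.10, 3 fell adjusted over the list alone, adjusted p = 0.124) and urothelium (0.63, 5 of 5 above 0, adjusted p = 0.0589) were not called. Without castrated genistein array 2, 144 genes passed (28 higher, 116 lower). Without arrays 1 and 3, 0 genes passed. The seminal vesicle and lymphocyte lists were still called by camera at the preset correlation, with 1 array against 3, at -0.56 (adjusted p = 0.0392) and -0.34 (adjusted p = 0.0400), while protein folding, fatty acid synthesis, adipocytes and skeletal muscle were not called, at -0.09, 0.19, 0.0035 and 0.01. Leaving out castrated vehicle array 1, 2 or 3, or castrated genistein array 1 or 3, also ended calls of the lymphocyte, fatty acid, adipocyte or skeletal muscle lists. The lymphocyte call also ended without a filter on dim probes, with a strict filter, with the mean of a gene's probes and with only the arrays compared, and the fatty acid call with the mean of a gene's probes. Without a filter the seminal vesicle list was called at a median of -0.29.

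In intact males genistein raised 1 gene, the water channel Aqp8, by 1.69 log2 units (SE 0.21, adjusted p = 0.0495), or 3.23-fold. Its signal was 7.47 ± 0.39 (SD, n = 3) with genistein and 5.77 ± 0.07 (SD, n = 3) with vehicle, and its second probe changed by 2.03. In a limma fit over all kept probes neither probe passed (adjusted p = 0.0590 and 0.0743), and both read the same samples. In castrated males Aqp8 read 5.20 ± 0.27 with genistein and 4.95 ± 0.27 with vehicle. Pbsn had a log2 change of 0.03 (SE 0.31, adjusted p = 0.993), Esr1 of 0.23 and Esr2 of 0.15. A total of 1141 genes had an unadjusted p under 0.05, and groups did not overlap for 10.7% of genes against 10% by chance. Aqp8 kept log2 changes of 0.95 to 1.91 under every alternative, but missed the threshold under 9 of 18, at adjusted p of up to 0.641, among them those without intact vehicle array 1, 2 or 3 and without intact genistein array 2. Without intact genistein array 1, 19 genes passed. With the authors' processed values 1 gene passed, but not Aqp8 (adjusted p = 0.0782).

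Camera called 3 lists for genistein in intact males, with 0 members past the threshold over all genes or adjusted over the list alone. Of the 10 ways to split these arrays 3 against 3, the real one included, 9 called as many lists. Cell cycle genes were higher (20 of 23 above 0, median 0.23, adjusted p = 0.00147, adjusted p = 0.857 with an estimated correlation), led by the mitotic kinase Aurka at 0.79 (SE 0.23), Cdc20 at 0.43, Cdc6 at 0.30 and Plk1 at 0.36. Smooth muscle markers were higher (11 of 12, median 0.16, adjusted p = 0.0240, adjusted p = 0.938 with an estimated correlation; Smtn 0.50, Cnn1 0.68). Cholesterol synthesis genes were lower (12 of 14 below 0, median -0.21, adjusted p = 0.00874, adjusted p = 0.938 with an estimated correlation; Sqle -0.29, Cyp51 -0.27, Nsdhl -0.42). Secretory proteins had a median of -0.004, androgen receptor targets -0.05, estrogen-responsive genes -0.02 and seminal vesicle transcripts -0.85, none of them called. The cell cycle call ended without intact genistein array 3 (median 0.10), the cholesterol call without intact vehicle array 2 or genistein array 1 (-0.11 and -0.14), and the smooth muscle call under median scaling and without vehicle array 1 or 3 or genistein array 2 or 3.

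**Figure D3:**
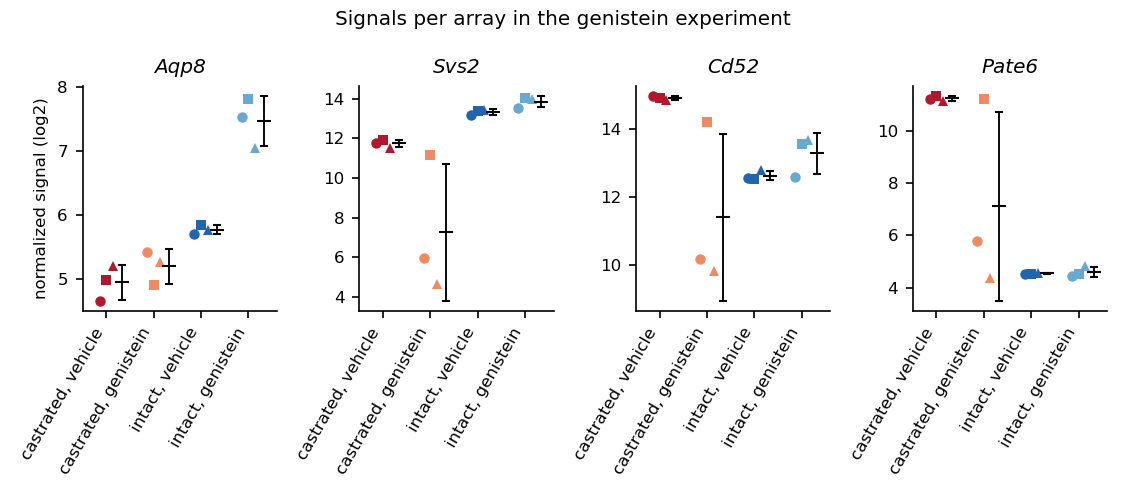
Normalized log2 signal (y axis) of Aqp8, Svs2, Cd52 and Pate6 on each array of the 4 groups of the genistein experiment (x axis), with the replicate number as the shape of a point and bars for the mean and SD, n = 3 per group. Aqp8 read 7.05 to 7.82 in intact genistein males and 5.70 to 5.85 in intact vehicle males, and Svs2 read 5.97, 11.17 and 4.65 on castrated genistein arrays 1, 2 and 3.

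The difference between the genistein responses of castrated and intact males was tested directly. Cholesterol synthesis genes responded more upward in castrated males, by a median of 0.36 (14 of 14 above 0, adjusted p = 0.000848, adjusted p = 0.857 with an estimated correlation), as did adipocyte markers, by 0.67 (9 of 9, adjusted p = 0.00874, adjusted p = 0.938 with an estimated correlation). Smooth muscle markers responded more downward, by -0.49 (10 of 12 below 0, adjusted p = 0.00156, adjusted p = 0.938 with an estimated correlation; Smtn -0.71, Myh11 -0.75), as did lymphocyte markers, by -0.39 (6 of 6, 2 lower adjusted over the list alone, adjusted p = 0.0111, adjusted p = 0.642 with an estimated correlation; Cd52 -4.15). Limma called 0 genes (lowest adjusted p = 0.153, for Cpsf4l), with 1122 at an unadjusted p under 0.05, and fry called 0 lists. Of 100 splits of the arrays, the real one included, 77 called as many lists. Pbsn had 0.33 (SE 0.44), Esr1 0.18 and Esr2 -0.31. Without castrated genistein array 2, 79 genes passed, and without intact genistein array 1, 3 genes. Without castrated genistein arrays 1 and 3 the smooth muscle and adipocyte lists were not called, at -0.27 and 0.30. Leaving out castrated vehicle array 1 or 2, castrated genistein array 1, intact vehicle array 2 or intact genistein array 1 or 3 ended the lymphocyte or adipocyte call.

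With estradiol, camera at the preset correlation called prostate secretory proteins lower as a group in intact males, and no single gene passed the threshold. Of the 14 secretory proteins 13 were below 0, with a median log2 change of -0.26 (adjusted p = 0.00874 in camera, adjusted p = 0.318 with an estimated correlation; 0 members passed over all genes or adjusted over the list alone). The 4 estradiol arrays had list scores of -0.40 to -0.08 against -0.04 to 0.42 on the 5 vehicle arrays. Estradiol array 1 stood apart at -0.40, with the other 3 at -0.11 to -0.08. Pbsn had a log2 change of -0.54 (SE 0.30, adjusted p = 0.780), the secretory protein Pate4 -0.33 (SE 0.14), the transglutaminase Tgm4 -0.26 (SE 0.13) and lactotransferrin Ltf -0.97 (SE 0.62). Ltf had estradiol array 1 at 10.0 and the other 3 at 13.02 to 13.19. Esr1 had -0.16 (SE 0.14) and Esr2 0.49 (SE 0.29). Limma called 0 of 15088 genes (lowest adjusted p = 0.656, for Setd3), with 1044 at an unadjusted p under 0.05. Groups of 4 and 5 arrays did not overlap for 2.82% of genes, against 1.59% by chance. Fry did not call the secretory list (adjusted p = 0.0895). All 100 splits of the arrays that were run, the real one included, called at least 1 list, and other splits called up to 12.

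Vehicle arrays of the estradiol experiment lie on 3 chips and estradiol arrays on 1 of them. With the chip as a fixed block, and on that chip alone (4 estradiol and 2 vehicle arrays), the secretory list had a median of -0.19 (adjusted p = 0.113 and 0.108) and Pbsn a log2 change of -0.04 (adjusted p = 0.979 and 0.981). On that chip 0 genes and 7 lists were called, with immediate early genes (0.29), lymphocytes (0.36), macrophages (0.32) and smooth muscle (0.33) higher. The others were lower, protein folding (-0.30), luminal epithelial markers (-0.28) and androgen receptor targets (-0.11). These calls were made in camera at the preset correlation alone. Seminal vesicle transcripts had the widest median there, -1.325, and were not called (adjusted p = 0.0665 in camera). Vehicle array 1, which stood apart in the experiment, was 1 of the 2 controls. Over all 9 arrays these 7 lists were not called, with luminal epithelial markers at -0.16 (10 of 13 below 0, adjusted p = 0.112) and smooth muscle at 0.22 (10 of 12 above 0, adjusted p = 0.111). Also not called were estrogen-responsive genes (0.04), squamous differentiation (-0.05), cell cycle genes (-0.07) and the remaining lists other than the secretory proteins.

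**Figure D4:**
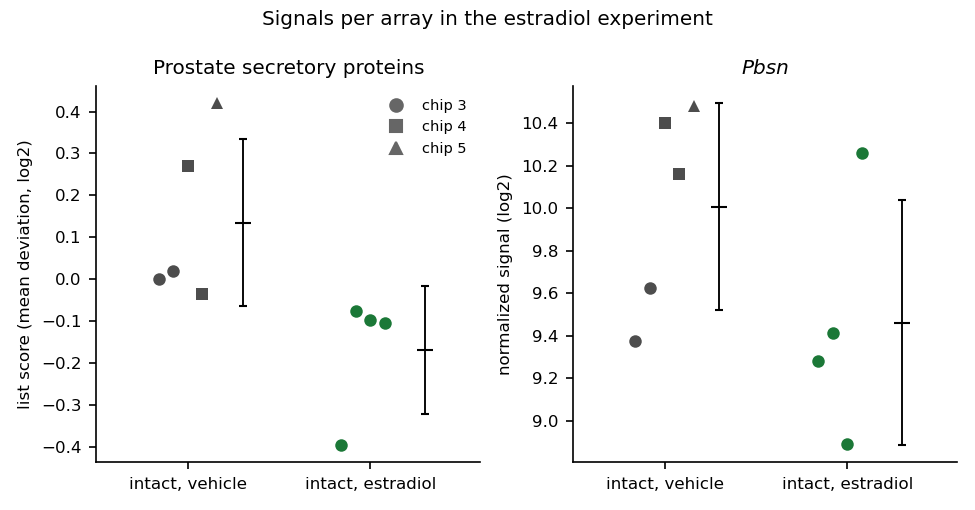
List score of the 14 prostate secretory proteins (left y axis, mean log2 deviation from each member's mean over the experiment) and normalized log2 signal of Pbsn (right y axis) on each array of intact males given vehicle (n = 5) or estradiol (n = 4), with the chip as the shape of a point and bars for the mean and SD. The 4 estradiol arrays score -0.40 to -0.08 and the 5 vehicle arrays -0.04 to 0.42, while Pbsn shifts by -0.04 on chip 3 alone.

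Genistein and estradiol responses of intact males were compared in 1 fit, with doses, days of treatment and vehicles that differed between the experiments. Cell cycle genes were higher with genistein relative to estradiol (21 of 23 above 0, median 0.30, adjusted p = 0.00121, adjusted p = 0.789 with an estimated correlation; Aurka 0.91, Mcm6 0.95, Mcm4 0.38), with 0 members past the threshold over all genes or adjusted over the list alone. Limma called 0 genes, with Aqp8 lowest (adjusted p = 0.0605) and 1027 genes at an unadjusted p under 0.05. Fry called 0 lists, and all 100 splits of the arrays that were run called at least as many lists as the real one. Aqp8 read 6.65 ± 0.33 (SD, n = 4) with estradiol and 6.80 ± 0.25 (SD, n = 5) with its vehicle. Secretory proteins had a median difference of 0.41 (11 of 14 above 0, adjusted p = 0.113), Pbsn 0.59 (SE 0.48), Esr1 0.38 and Esr2 -0.28. A single gene passed under 6 alternatives and without intact genistein array 3, and without vehicle array 2 of the estradiol experiment 8 genes passed.

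Across genes, which are not independent replicates, the changes were compared in 5 correlations. Castration and estradiol changes, which share no arrays, had Pearson's r of 0.17 and Spearman's rho of 0.18 over 14425 genes, where simulated unchanged groups gave r from -0.34 to 0.26. The covariance was 0.0232, and 3 of 100 draws had a covariance as far from the mean of the draws. The draws held no castration effect, and covariance grows with the size of the castration changes. That share therefore cannot decide whether the castration and estradiol changes are related, and r lay within the simulated range. Without vehicle array 1 of the estradiol experiment r was 0.08, and on the shared chip 0.23. Castration and genistein changes in intact males, which share the intact vehicle arrays, had r of 0.29 where simulation gave 0.48 (-0.10 to 0.85), with a covariance of 0.0403 against 0.0282. Castration and genistein changes in castrated males, which share the castrated vehicle arrays, had r of -0.15 where simulation gave -0.48 (-0.85 to 0.35), with a covariance of -0.0251 against -0.0262. For these comparisons 42 and 92 of 100 draws had a covariance as far from the mean of the draws. Genistein and estradiol changes in intact males had r of 0.04, where simulation gave -0.28 to 0.28. The genistein changes in castrated and intact males had r of 0.05, where simulation gave -0.50 to 0.46.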

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

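Most single arrays named here stood apart from the other arrays of their group by a Dixon test, run on 78 sets of values, of which 9 gave an array. The test needs at least 4 values, so the genistein experiment, with 3 arrays per group, was not covered. It names an array in about 5% of sets by chance, though the sets hold the same arrays and are not independent. Vehicle array 1 of the estradiol experiment stood apart in its mean correlation with its group (0.9562, the other 4 at 0.9732 to 0.9796) and on the first axis of variation (-63.64, the others at 9.749 to 22.83). Its apoptosis score was 0.3127 (others -0.08437 to -0.02082), its urothelial marker score -0.8926 (others 0.01823 to 0.3633) and its skeletal muscle score -0.6753 (others 0.2285 to 0.3926). Vehicle array 3 of that experiment had a cholesterol synthesis score of -0.1254, where the other 4 vehicle arrays had 0.06874 to 0.1072.

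Estradiol array 1 had the lowest secretory protein score, -0.3965 against -0.1056 to -0.07532 on the other 3 estradiol arrays. Its skeletal muscle score was -0.8917 (others 0.05736 to 0.19), and its signal of lactotransferrin, Ltf, was 10 on the log2 scale (others 13.02 to 13.19).

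Camera at a preset correlation of 0.01 called 4 gene lists for the difference between the genistein responses of castrated and intact males. None was called with an estimated correlation (adjusted p = 0.642 to 0.938) or with fry, and 77 of 100 splits of the arrays called as many lists. The median difference, castrated minus intact, was 0.3619 for cholesterol synthesis, -0.4899 for smooth muscle markers, -0.3869 for lymphocyte markers and 0.6699 for adipocyte markers. Castrated genistein arrays 1 and 3, which lacked much of the seminal vesicle signal of the other castrated arrays, enter all of these differences; without them smooth muscle markers (-0.27) and adipocyte markers (0.30) were not called, and the cause was not tested.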

How the results depend on the processing

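Alternatives for the gene counts were set before the data were examined, apart from the fits without castrated genistein arrays 1 and 3, where the lone array left was taken to vary like the other groups, and castration in genistein-treated males. Of those for list counts, only fry and the estimated correlation were set before. Where a call changed, the cause was not tested.

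For genistein in castrated males 0 genes passed, and 5 with array weights. With 1 array left out the count ran from 0 to 144, with 144 without castrated genistein array 2. For genistein in intact males the count of 1 became 0 with cyclic loess, 0 without a filter on dim probes and 0 with only the arrays compared. With 1 array left out it ran from 0 to 19, with 19 without intact genistein array 1 and 0 without intact vehicle array 1, 2 or 3 or intact genistein array 2. The castration count of 3259 ran from 2037, without castrated vehicle array 1, to 2898 with 1 array left out. The difference between the genistein responses went from 0 to 79 genes without castrated genistein array 2 and to 3 without intact genistein array 1. For estradiol 0 genes passed in every alternative. For genistein against estradiol 1 gene passed with no background correction, 1 with an offset of 50, 1 under median scaling, 1 with a strict filter, 1 with the mean of a gene's probes and 1 with array weights; with 1 array left out the range was 0 to 8, with 8 without vehicle array 2 of the estradiol experiment and 1 without intact genistein array 3.

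The 6 lists called for genistein in castrated males became 10 without a filter, 0 with an estimated correlation and 0 with fry; with 1 array left out they ran from 4 to 10, with 10 without castrated genistein array 2. The 3 lists for intact males became 6 with no background correction, 7 without a filter, 0 with an estimated correlation and 0 with fry. With 1 array left out they ran from 2 to 9, with 9 without intact vehicle array 2 or intact genistein array 2. The 10 castration lists became 0 with an estimated correlation and ran from 9 to 13 with 1 array left out. The 4 lists for the difference between the genistein responses became 2 without castrated genistein arrays 1 and 3, 0 with an estimated correlation and 0 with fry, and ran from 3 to 7 with 1 array left out, with 7 without intact genistein array 2.

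The 1 list for estradiol became 3 under median scaling, 2 without a filter, 2 with array weights, 7 with the chip as a fixed block, 7 on the chip that holds both groups, 0 with an estimated correlation and 0 with fry. It ran from 1 to 4 with 1 array left out: 4 without vehicle array 4, 3 without estradiol array 1, and 2 without vehicle array 1, vehicle array 3 or estradiol array 4. The 1 list for genistein against estradiol became 2 with no background correction, an offset of 50, no filter, the mean of a gene's probes, the authors' values, array weights, the shared chip and separate normalization. It became 3 under median scaling and cyclic loess, 0 with an estimated correlation and 0 with fry. With 1 array left out it ran from 1 to 5: 5 without intact genistein array 2, 4 without intact vehicle array 2 of the genistein experiment or vehicle array 1 of the estradiol experiment, 3 without intact genistein array 1 or estradiol array 4, and 2 without intact vehicle array 3 of the genistein experiment, estradiol array 2 or estradiol array 3.

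With the replicate number as a block, 0 genes passed for genistein in intact males, and 5 lists were called there and 3 for genistein against estradiol. Whether the numbers pair the samples could not be decided with so few arrays per group. Over arrays of the same number in the compared groups, correlations of deviations from the group means ran from -0.2765 for genistein in intact males to 0.343 for estradiol. Most arrays were not closest to the vehicle array of their own number, but castrated genistein arrays 2 and 3 and estradiol arrays 1 and 3 were.

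The correlation of castration and genistein changes in castrated males moved to -0.08678 with no background correction and ran from -0.2191 to -0.09432 with 1 array left out. That of castration and genistein changes in intact males ran from 0.1191 to 0.4272. That of castration and estradiol changes was 0.2302 on the shared chip and ran from 0.08028 to 0.2574. That of genistein and estradiol changes in intact males was 0.1511 on the shared chip and ran from -0.03708 to 0.1068, and that of the genistein changes in castrated and intact males ran from -0.04769 to 0.1362.

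Several list calls ended under alternatives: for genistein in castrated males those of lymphocyte markers in 9 of 21 and of fatty acid synthesis in 7 of 21, and for genistein in intact males that of smooth muscle markers in 7 of 20. Without castrated genistein arrays 1 and 3 the adipocyte median for genistein in castrated males was 0.003512 and not called. In genistein-treated males the castration changes of Il4i1, Cd79b and Sqle were -0.002185, -0.003793 and 0.1112, opposite in sign to those in vehicle-treated males, and none passed.

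Of the values of genes named for castration, 2244 of 2444 kept their side of the threshold, 160 no longer passed and 37 newly passed. For genistein in intact males 1980 of 1991 did, in castrated males 2054 of 2062, for the difference between those responses 2650 of 2657, and for estradiol and for genistein against estradiol all 2473 and 3038. With 42.3% to 47.0% of probes above background, genes near or below it were left untested.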

Other observations

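Transcripts that set castrated genistein arrays 1 and 3 apart included secretory and epithelial genes besides those of the seminal vesicle. Lcn2, an iron-binding secretory protein, read 8.18 and 8.19 on those arrays, 12.13 on castrated genistein array 2 and at least 12.07 on castrated vehicle arrays. The epithelial transcription factor Elf5 read 7.43 and 8.53 against 10.79 on array 2, and the antibacterial protein Pglyrp1 read 9.01 and 9.81 against 12.27. Pate4, a secreted protein of the male tract, read 11.57 and 9.50 against 15.06.

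The tests of the 3 patterns weighed here were chosen after the results were seen, apart from the chip layout, which was set before. A total of 25 transcripts were at least 2 log2 units lower on castrated genistein arrays 1 and 3 than on every castrated vehicle array. Between vehicle-treated groups, 16 of them were called higher in castrated than in intact males and 0 lower. High values on castrated vehicle arrays helped to select these transcripts, which favours such a rise, so the counts decide nothing. A gland or lobe held by some dissections and not others is a possible cause: in the estradiol experiment 22 of these transcripts moved together with a mean pairwise correlation of 0.439, where 1000 random sets reached at most 0.222. Transcripts that move together for any other reason would also exceed random sets, so this test cannot single out that cause. The correlation was not computed without vehicle array 1, which stood apart. A like fall in every genistein-treated castrated male was not seen, since the seminal vesicle score lay -0.68 from the vehicle mean on array 2 (vehicle SD 0.914) and -2.91 and -3.74 on arrays 1 and 3. A smaller fall on array 2 stays open. Without arrays 1 and 3 the seminal vesicle median was still negative, and a single array cannot decide it.

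Macrophage, lymphocyte and endothelial markers could be higher after castration because epithelium shrinks and other cells take a larger share. If that were the whole cause, smooth muscle markers would rise with macrophage markers. The macrophage score minus the smooth muscle score was higher in castrated males by 1.44 (exact p = 0.00216, 12 arrays). This pair was picked after its values were seen, and that p is the lowest that 924 splits can give. It shows only that castrated and intact arrays did not overlap. Among vehicle-treated males this score averaged 0.653 (SD 0.245) with castration and -0.654 (SD 0.0655) without. Smooth muscle was lower over the 12 arrays at -0.494 (adjusted exact p = 0.00864), though its list was not called in vehicle-treated males alone (mean -0.290). A larger share of other cells stays open as part of the cause. Over the 12 arrays, genistein-treated ones included, scores of fibroblasts (0.40), adipocytes (0.63) and urothelium (0.82) were higher and that of luminal cells lower (-0.21). Not all lists went that way, as skeletal muscle (-0.276), red blood cells (-0.151) and basal cells (0.079) did not pass (adjusted exact p = 0.21 to 0.669). A difference between chips could not be told apart, as 0 chips hold both castrated and intact arrays.

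For the secretory proteins with estradiol, a difference between chips could explain part: the median was -0.1863 on the chip that holds both groups and was not called there. Lower androgen-driven expression would also lower other genes that castration lowers. Such genes were taken as those lowered by castration by at least 1 log2 unit and measured in the estradiol experiment, with the secretory list left out. The median estradiol change of these 467 genes was -0.0745, with 35 of 126 splits of the arrays as low. It ran from -0.183 to -0.0117 (without vehicle array 1) with 1 array left out. On the shared chip it was -0.261, with 2 of 15 splits as low. For 401 genes that castration raised by at least 1 log2 unit the median was 0.134, with 10 of 126 splits as high, and 0.0553 without vehicle array 1. On the shared chip it was 0.198, with all 15 splits at or below it. The shared chip has too few splits to judge these medians, and both explanations stay open.

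Splits of the same arrays into other groups were set before the data were examined. With 3 against 3 arrays there are 10 splits, too few to judge a count. For genistein in castrated males the real split gave 0 genes and the highest other 1, and all 10 splits must reach 0; for lists 6 and 11, with 6 splits as many. For genistein in intact males it gave 1 gene and the highest other 5, with 3 as many; for lists 3 and 9, with 9 as many. For castration it gave 3259 genes and the highest other 0, with 1 as many; for lists 10 and 11, with 2 as many.

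In the other comparisons 100 splits were run. Of these 77 gave as many lists as the real 4 for the difference between the genistein responses (up to 12), 100 as many as the real 1 for estradiol (up to 12) and 100 as many as the real 1 for genistein against estradiol (up to 14). A real count of 0 genes decides nothing, since all 100 splits must reach it; the highest counts of other splits were 2, 15 and 5 genes in the same order. Splits that call several times the real count could reflect a structure of the samples other than treatment or, for lists, genes that move together, as no list was called with an estimated correlation. Neither was tested.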
